A study of Mus musculus with 18 samples.

How the data were processed

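RNA was sequenced from mouse primary tendon cells, adult or neonatal, in 18 libraries of 6 groups of 3. Per the labels' protocols, tendons were digested with collagenase, cells were passaged and frozen, thawed cells were cultured for 3 days, and they then received complete medium mixed with T cell medium or with supernatant from stimulated adult or neonatal T cells. Per the labels' protocols, RNA was extracted with Trizol and polyadenylated RNA made into NEBNext Ultra II libraries read from both ends. The duration of the treatment and the mouse strain are not given in the sources used here. Per the submitters' processing notes, reads were counted with kallisto against GRCm39 and handled with limma 3.56.2, and the kallisto version is not given in the sources used here.

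The deposited table holds log2 CPM (each count divided by its library's total) for 14391 genes in the 18 libraries, as the authors made it, and no raw count was used here. All libraries share a lowest value of -2.9787 log2 CPM (0.1269 CPM), the CPM of a library sum to 999134 to 1001152, and every gene has at least 1 CPM in 3 libraries. The values thus carry a scaling to the total count alone. Depth was estimated as the total at which low values, less an offset of 2 reads, fall on whole reads to within 0.02 reads, which held for 11.1 to 22.1% of them against 7.7 to 12.4% at the best other total (11.1 against 9.9%, the least clear, in neonatal-cell adult-supernatant library 3). It gave 12.7 to 17.7 M reads (mean 15.8, and 15.77 from the lowest value), with an error of at most 0.16% when tested on simulated data. A count of 0 was set at 3 reads of the library, 0.169 to 0.237 CPM, which covers counting error only. Of the row names, 14190 match a symbol or synonym of the RefSeq table (GRCm38.p6), 21 are spreadsheet dates, 1 is repeated and 3 lines equal an earlier line. The reference annotation is GENCODE M21 on GRCm38, another build than the file's, and served only for names, lengths, chromosome and sequence matches.

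Groups and comparisons follow the labels: each supernatant against media in adult and in neonatal cells, neonatal against adult supernatant in each, neonatal against adult cells in media, and the interaction of cell age with each supernatant. Genes were fitted with limma 3.58.1 in R 4.3.3 (lmFit, contrasts.fit and eBayes with trend, two-sided) on the deposited log2 CPM of all libraries, with 12 residual and 4.6 prior degrees of freedom, and called at a Benjamini-Hochberg adjusted p under 0.05. When tested on simulated data with 14391 genes, it recovered 25.4, 67.2 and 93.9% of genes changed by 0.5, 1 and 2 log2 units for adult cells with adult supernatant, with 5.34% of calls on unchanged genes, and 7.46, 56.7 and 81.8% for the interaction with adult supernatant, with 3.96% on unchanged genes. Principal components and correlations used the same values.

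The 29 gene lists, fixed before the data were examined, hold 520 memberships, of which 460 were measured, 4 under another symbol. They cover interferon-gamma, type I interferon, MHC class I and II, NF-κB, chemokines, cytokines, IL-17, IL-4 and IL-13, tendon, collagens, proteases, myofibroblast and TGF-beta, cell cycle, p53, glycolysis and hypoxia, respiratory chain, cholesterol, oxidative stress, unfolded protein, cartilage and bone, and fetal growth genes, and markers of T cells, macrophages, endothelium, mural cells, skeletal muscle, Schwann cells and keratinocytes. The 28 with at least 5 measured members were tested with camera (preset correlation 0.01), and again with an estimated correlation and with fry. Another 6 lists were chosen after seeing the data. Levels of a list are means of log2 CPM per library. Genes named in the text follow a rule fixed beforehand: the 6 largest rises and falls among called genes of at least 5 CPM with no overlap between groups and no predicted or clone name, a set of genes named whatever their values, up to 4 members of each list with the smallest p, and for interactions the 10 genes of each direction with the smallest p. Some genes that the rule picks are not used here.

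Alternatives were TMM scaling (an unweighted trimmed mean computed here), quantile normalization, pseudocounts of 0.1 and 1 CPM, a filter of 5 CPM in 3 libraries (11293 genes), a mean of at least 3 log2 CPM (9411 genes), no trend, array weights, only the compared groups, a replicate block, a 2-fold limit, and leaving out each library or both media libraries of high type I interferon level. Sequence matches used blastn 2.17.0. Tables and plots were made with Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9. Raw reads were not analysed here.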

Results

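RNA from cultured mouse tendon cells was measured in 18 libraries that fell into 6 groups of 3. Cells from adult or neonatal tendons received medium alone, medium conditioned by stimulated adult T cells, or medium conditioned by stimulated neonatal T cells (here supernatant). The series asks, from its title, whether neonatal tendon cells resist inflammation by themselves and which part factors secreted by T cells play. The depth estimated from the values ran from 12.7 to 17.7 M reads per library. At these depths 3 reads correspond to 0.169 to 0.237 CPM. Ribosomal-protein genes took 1.86 to 2.04% of all CPM in the adult-cell groups and 2.37 to 2.76% in the neonatal-cell groups. The labels do not say whether libraries of a group came from separate animals or cultures.

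The first principal component held 54.0% of the variance, the next 13.3% and the one after 5.6%. Along the first, cells of each age ran from media through neonatal to adult supernatant, and the next separated neonatal from adult cells. Correlations across genes were 0.958 to 0.982 within groups (median 0.976) and 0.825 to 0.966 between groups (median 0.936). A pair of media libraries stood apart in the type I interferon list, whose mean level was 3.08 log2 CPM in library 2 of adult cells in media against 1.49 and 1.23 in libraries 1 and 3. In neonatal cells in media it was 3.12 in library 1 against 0.38 and 0.07 in libraries 2 and 3. Library 3 of neonatal cells with neonatal supernatant had a mean level of 3.55 in the IL-17 target list, against 5.08 and 5.54 in libraries 1 and 2.

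**Figure D1:**
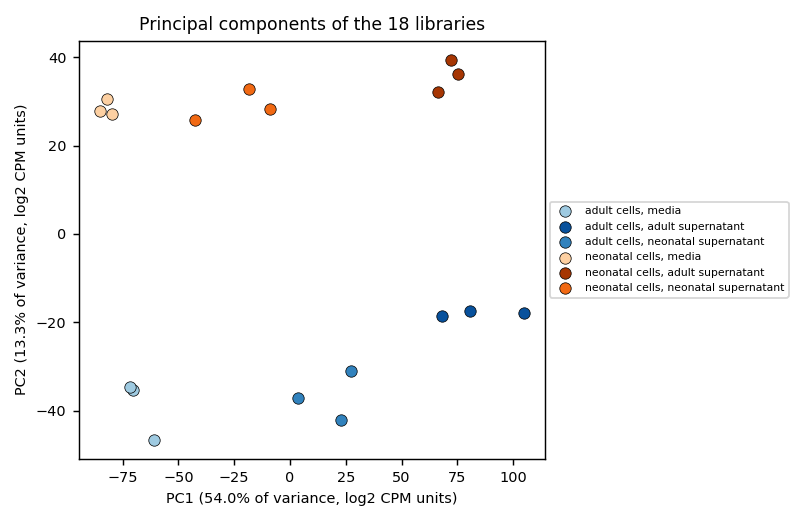
Scores of the 18 libraries on the first principal components of log2 CPM, with the share of variance on each axis and 1 point per library coloured by group.

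Supernatant from adult T cells changed more genes than supernatant from neonatal T cells in cells of either age. Against media, 7490 of 14391 genes passed the threshold in adult cells with adult supernatant and 3929 with neonatal supernatant. In neonatal cells the counts were 6875 and 2638. Quantile normalization shifted the median of all genes by -0.12 and -0.18 with adult supernatant in adult and neonatal cells, and by 0.13 between the supernatants in neonatal cells. It turned the split of the calls from 54.1% higher to 3139 higher and 4395 lower (41.7% higher) in adult cells with adult supernatant, and from 59.1% to 1649 higher and 1900 lower (46.5% higher) with neonatal supernatant. For neonatal cells the split went from 59.3% to 2711 higher and 4098 lower (39.8% higher) with adult supernatant, and from 58.5% to 1090 higher and 1164 lower (48.4% higher) with neonatal supernatant. In adult cells with adult supernatant, a filter of 5 CPM in 3 libraries also turned it, to 2865 higher and 3189 lower. With a mean of at least 3 log2 CPM it was 2269 and 2810, with neonatal supernatant 1301 and 1371, and in neonatal cells with adult supernatant 2220 and 2344. Fold changes come from limma on 3 libraries per group, and each adjusted p from limma with Benjamini-Hochberg adjustment. Values after gene names are log2 fold changes ± standard error, and medians and means of lists are of log2 fold changes. Where a list has no second count, as many members passed when adjusted over the list alone.

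**Figure D2:**
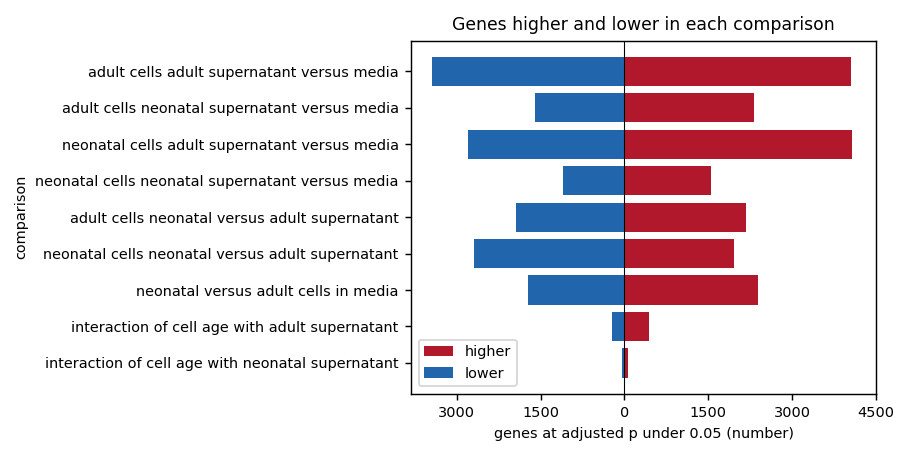
Number of genes higher (bars to the right) and lower (bars to the left) at an adjusted p under 0.05 in each of the 9 comparisons. The count was 7490 for adult cells with adult supernatant and 123 for the interaction with neonatal supernatant.

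In adult tendon cells, adult T cell supernatant raised genes induced by interferon-gamma and lowered genes of the contractile and matrix programme. Nos2 (9.75 ± 0.38), Gbp6 (9.41 ± 0.59), Iigp1 (8.56 ± 0.65) and Cxcl9 (8.45 ± 0.46) were among the 6 largest rises: inducible nitric oxide synthase, interferon-induced GTPases and a T cell chemokine. Gbp4, at 0 in all media libraries, was at least 2180-fold higher when the media are set at 3 reads per library. The largest falls were in Eln (-7.86 ± 0.58), Myh11 (-7.65 ± 0.96), C1qtnf3 (-5.45 ± 0.21), Sema3d (-5.02 ± 0.43), Aspn (-4.98 ± 0.38) and Npr3 (-4.97 ± 0.25), among them elastin, smooth muscle myosin and the small proteoglycan asporin. Nos2 went from 3.93 ± 0.763 to 3350 ± 204 CPM (mean ± SD, n = 3). Adjusted p was at most 3.9e-06 for these genes. Tgtp2 (8.74 ± 0.46) also rose, but it is nearly identical to Tgtp1, and the Gbp genes resemble each other, so their single values are uncertain.

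Of the interferon-gamma response genes, 25 of 25 rose, median 5.72 (camera adjusted p = 2.43e-16, with estimated correlation p = 0.0749), among them Irf1 (4.58 ± 0.21), Cd274 (5.72 ± 0.28) and Cxcl10 (6.70 ± 0.44), which are a transcription factor, the checkpoint ligand PD-L1 and a chemokine. Of the type I interferon genes, 19 of 21 rose and 1 fell, median 3.69 (camera adjusted p = 9.19e-05, with estimated correlation p = 0.418), including Zbp1 (6.62 ± 0.81), Bst2 (3.79 ± 0.60) and Oas3 (3.94 ± 0.68). For MHC class I and peptide processing, 19 of 19 rose, median 3.31 (camera adjusted p = 4.7e-15, with estimated correlation p = 0.0916), with H2-K1 (4.86 ± 0.25) and H2-D1 (3.80 ± 0.21), while H2-Q6 (7.90 ± 0.32) and H2-Q7 (7.77 ± 0.36) share near-identical sequence and are uncertain. For MHC class II, 5 of 7 rose, median 4.13 (camera adjusted p = 0.00162, with estimated correlation p = 0.0711), with Cd74 (6.22 ± 0.43) and Ciita (4.13 ± 0.67). H2-Aa was at least 18.2-fold higher. Camera compared each list with all other genes, at a preset correlation of 0.01, and its p-values are adjusted over 28 lists. The p after it uses a correlation estimated from the data and is adjusted likewise. No call held with an estimated correlation for any of the 19 lists called here, nor for any list called in the responses of neonatal cells or in the interactions.

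Inflammatory mediators and the glycolysis and oxidative stress genes rose as well. Of the NF-κB targets, 17 of 19 rose, median 1.87 (camera adjusted p = 2.39e-09, with estimated correlation p = 0.0749), and of the chemokines, 11 of 15 rose and 2 fell, median 4.44 (camera adjusted p = 7.96e-07, with estimated correlation p = 0.0916). Ccl2 (4.00 ± 0.12), Ccl7 (2.83 ± 0.10) and Ccl8 (6.30 ± 0.21), which attract monocytes, rose. Of the cytokines and growth factors, 15 of 21 rose and 1 fell (15 and 2 adjusted over the list alone), median 1.41 (camera adjusted p = 0.000636, with estimated correlation p = 0.0749), led by Il6 (5.97 ± 0.51) and Lif (3.86 ± 0.23). For IL-17 targets, 14 of 15 rose, median 3.37 (camera adjusted p = 5.33e-09, with estimated correlation p = 0.11), with Lcn2 (7.61 ± 0.73), Cxcl5 (4.44 ± 0.28) and Cebpd (2.59 ± 0.16). For IL-4 and IL-13 targets, 6 of 9 rose and 1 fell, median 3.18 (camera adjusted p = 0.00506, with estimated correlation p = 0.0916), the rises including Il13ra2 (7.69 ± 0.43) and Ccl11 (5.30 ± 0.31) and the fall being periostin, Postn (-2.96 ± 0.16). Of the glycolysis and hypoxia genes, 17 of 17 rose, median 1.75 (camera adjusted p = 4.09e-13, with estimated correlation p = 0.0749), with Slc2a1 (2.84 ± 0.15) and Egln3 (4.39 ± 0.23), a glucose transporter and an oxygen-sensing hydroxylase. Of the oxidative stress genes, 12 of 13 rose, median 1.21 (camera adjusted p = 1.85e-07, with estimated correlation p = 0.0528), with Hmox1 (2.33 ± 0.07) and Slc7a11 (3.20 ± 0.15). Mmp3 (4.38 ± 0.43), Mmp13 (2.58 ± 0.45) and Ptgs2 (2.39 ± 0.21), matrix-degrading enzymes and the inducible prostaglandin synthase, also rose. At most, adjusted p reached 0.00013 for the genes named here.

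Tendon and matrix genes mostly fell. Of the tendon genes, 4 of 21 rose and 15 fell, median -1.42 (camera adjusted p = 2.14e-06, with estimated correlation p = 0.0749), the falls including Scx (-2.24 ± 0.22), Tnmd (-2.46 ± 0.30), Fmod (-2.73 ± 0.13) and Col14a1 (-4.90 ± 0.25), a tendon transcription factor and 3 matrix or membrane proteins, while Tnc (3.01 ± 0.16), tenascin C, rose. Mkx did not pass the threshold (0.03, adjusted p = 0.941). Of the collagens and fibre assembly genes, 7 of 29 rose and 19 fell, median -0.95 (camera adjusted p = 3.18e-05, with estimated correlation p = 0.164), with Col1a1 (-1.64 ± 0.10), Col3a1 (-0.57 ± 0.15), Col5a1 (-2.32 ± 0.12) and Col6a1 (-2.24 ± 0.11). For myofibroblast and TGF-beta genes, 2 of 24 rose and 16 fell, median -1.27 (camera adjusted p = 1.37e-06, with estimated correlation p = 0.0932), with Acta2 (-2.83 ± 0.20), Cnn1 (-3.66 ± 0.22) and Tgfb2 (-4.35 ± 0.26). The proteases and inhibitors went both ways, as 8 of 26 rose and 9 fell (median -0.08, mean 0.22, camera downwards, adjusted p = 0.326). Cartilage and bone genes did so too, as 2 of 9 rose and 4 fell (camera adjusted p = 0.326), and Sp7, an osteoblast factor at 0 in all libraries with supernatant, was at least 9.84-fold lower. The largest adjusted p of the genes said to change was 0.00477.

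Cell cycle genes fell more often than they rose, and p53 and cholesterol genes mostly fell. Of the cell cycle genes, 4 of 32 rose and 16 fell (4 and 17 adjusted over the list alone), median -0.47 (camera adjusted p = 0.015, with estimated correlation p = 0.504), with Mki67 (-1.08 ± 0.18), and of the p53 and senescence genes, 2 of 18 rose and 16 fell, median -0.66 (camera adjusted p = 1.37e-06, with estimated correlation p = 0.0749), with Cdkn2b (-1.69 ± 0.08). In cholesterol synthesis, 1 of 20 rose and 11 fell (2 and 11 adjusted over the list alone), median -0.39 (camera adjusted p = 0.00182, with estimated correlation p = 0.348), with Hmgcs1 (-1.23 ± 0.09). In the unfolded-protein and amino-acid stress list, 2 of 16 rose and 8 fell, median -0.20 (camera adjusted p = 0.049, with estimated correlation p = 0.385). The unfolded-protein list missed the threshold without media library 1 (adjusted p = 0.0818), media library 3 (0.0749), adult-supernatant library 1 (0.0664) or adult-supernatant library 3 (0.0518). The respiratory chain gave no call, as 3 of 20 rose and 2 fell (median -0.02, mean 0.00, camera adjusted p = 0.722). Nor did fetal growth and imprinted genes, as 3 of 12 rose and 5 fell (camera adjusted p = 0.469). Igf2 (-1.41 ± 0.46) fell with adjusted p = 0.016, while Cdkn1c (-4.16 ± 0.30) fell and Hmga2 (1.58 ± 0.07) rose. Igf2 missed the threshold without media library 3 (adjusted p = 0.0899) or adult-supernatant library 3 (0.0894).

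Markers of other cell types went different ways with adult supernatant in adult cells. For mural-cell markers, 5 of 7 fell, median -1.85 (camera adjusted p = 0.00162, with estimated correlation p = 0.0932), with Cspg4 (-3.32 ± 0.26) and Pdgfrb (-1.85 ± 0.10). Of the T cell markers, 3 of 6 rose (camera adjusted p = 0.0665), including Il2ra (2.94 ± 0.50) and Cd4 (3.21 ± 0.58). The T cell list passed the threshold without media library 1 (adjusted p = 0.0388) or adult-supernatant library 3 (0.0375). For macrophage markers, 4 of 14 rose and 1 fell (2 and 1 adjusted over the list alone, camera adjusted p = 0.615), with Ptprc (2.51 ± 0.55) and Lyz2 (-1.36 ± 0.20). For endothelial markers, 1 of 10 rose and 2 fell (camera adjusted p = 0.433), for skeletal muscle, 2 of 5 rose and 1 fell (camera adjusted p = 0.722) and for Schwann cells, 1 of 6 rose and 1 fell (0 and 1 adjusted over the list alone, camera adjusted p = 0.722). Of the keratinocyte list, 4 members were measured and the list was not tested: Perp (-2.81 ± 0.17) fell and Cdh1 (3.02 ± 0.36) rose. The summed level of 64 odorant and vomeronasal receptor genes, chosen after their values were seen, was 37.2 CPM in adult cells in media, 439 CPM with adult supernatant (364, 679 and 274 CPM in libraries 1 to 3) and 158 CPM with neonatal supernatant. In neonatal cells these sums were 28.8, 361 and 88.9 CPM. In total, 7490 of 14391 genes passed the threshold, 4052 higher and 3438 lower, 3424 of them by at least 2-fold (2399 higher and 1025 lower).

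Supernatant from neonatal T cells raised chemokine genes and IL-17 targets in adult tendon cells. The largest rises were in Ccl11 (7.04 ± 0.31), Saa3 (5.72 ± 0.66), C3 (5.70 ± 0.38), Il13ra2 (5.57 ± 0.43), Serpina3i (5.33 ± 0.37) and Steap4 (5.11 ± 0.55): eotaxin, serum amyloid A, complement C3, the IL-13 decoy receptor, a protease inhibitor and a metalloreductase. The largest falls were in Eln (-5.73 ± 0.58), Lgr5 (-3.62 ± 0.47), Col8a2 (-3.43 ± 0.38), C1qtnf3 (-3.26 ± 0.21), Cilp (-3.18 ± 0.35) and Aspn (-3.15 ± 0.38), with elastin first and the others mostly matrix proteins. Adjusted p was at most 2.35e-05 for these genes. The question is how adult cells respond to factors from young T cells, and 3929 of 14391 genes passed the threshold, 2321 higher and 1608 lower, 1626 of them by at least 2-fold (1300 higher and 326 lower).

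Of the IL-17 targets, 13 of 15 rose, median 2.47 (camera adjusted p = 4.19e-11, with estimated correlation p = 0.128), with Lcn2 (4.18 ± 0.73) and Cxcl5 (4.16 ± 0.28), and of the chemokines, 11 of 15 rose and 1 fell, median 2.25 (camera adjusted p = 2.27e-10, with estimated correlation p = 0.0625), with Ccl2 (3.38 ± 0.12), Ccl7 (2.47 ± 0.10) and Ccl8 (4.89 ± 0.21). For IL-4 and IL-13 targets, 6 of 9 rose and 1 fell, median 2.33 (camera adjusted p = 4.38e-05, with estimated correlation p = 0.0625), with Il4ra (2.92 ± 0.11) and Cish (2.33 ± 0.21). Of the interferon-gamma genes, 22 of 25 rose (23 adjusted over the list alone), median 2.15 (camera adjusted p = 1.06e-10, with estimated correlation p = 0.128), with Irf1 (1.82 ± 0.21), Iigp1 (5.04 ± 0.65) and Cd274 (1.76 ± 0.28), and for MHC class I, 18 of 19 rose, median 1.46 (camera adjusted p = 2.08e-12, with estimated correlation p = 0.128). For MHC class II, 5 of 7 rose (median 1.63, or 1.30 with H2-Aa at its 3-read bound of at least 1.66-fold, camera adjusted p = 0.00625, with estimated correlation p = 0.0625). Mmp3 (3.41 ± 0.43), Mmp13 (1.86 ± 0.45) and Il6 (3.09 ± 0.51) rose. Ptgs2 (0.63 ± 0.21) passed with adjusted p = 0.0314. Ptgs2 missed the threshold without media library 2 (adjusted p = 0.177), neonatal-supernatant library 1 (0.135) or neonatal-supernatant library 3 (0.0753). Cxcl10 did not pass (0.77, adjusted p = 0.221). Of the type I interferon genes, 6 of 21 rose (11 adjusted over the list alone), median 1.59 (camera adjusted p = 0.0138, with estimated correlation p = 0.639). The type I interferon list missed the threshold without media library 3 (adjusted p = 0.119) or neonatal-supernatant library 2 (0.134).

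Tendon genes went both ways with neonatal supernatant in adult cells, as 5 of 21 rose and 10 fell, median -0.35 (camera adjusted p = 0.0385, with estimated correlation p = 0.38). The tendon list missed the threshold without media library 2 (adjusted p = 0.0513), media library 3 (0.067), neonatal-supernatant library 1 (0.0891) or neonatal-supernatant library 2 (0.0579). Falls included Tnmd (-1.62 ± 0.30) and Col12a1 (-0.84 ± 0.13), while Mkx (1.37 ± 0.27), Prg4 (1.28 ± 0.12) and Comp (0.78 ± 0.11) rose, a tendon transcription factor, lubricin and cartilage oligomeric matrix protein. Scx (-0.87 ± 0.22) and Col1a1 (-0.48 ± 0.10) fell, but Scx was at -0.93 with quantile normalization (adjusted p = 0.0676) and Col1a1 at 0.00 with quantile normalization (adjusted p = 1). Col3a1 (0.61 ± 0.15) rose. The collagen list gave no call, as 12 of 29 rose and 10 fell (median 0.00, mean -0.13, camera upwards, adjusted p = 0.872). Of the myofibroblast genes, 2 of 24 rose and 13 fell, median -0.55 (camera adjusted p = 0.000192, with estimated correlation p = 0.196), with Acta2 (-1.17 ± 0.20) and Tgfb2 (-2.33 ± 0.26). Of the p53 and senescence genes, 16 of 18 fell (17 adjusted over the list alone), median -0.58 (camera adjusted p = 7.57e-15, with estimated correlation p = 0.0258), with Cdkn2b (-1.27 ± 0.08), a cell cycle inhibitor. That was the list call that held with an estimated correlation here. Mki67 (0.11, adjusted p = 0.704) and Igf2 (-1.15, adjusted p = 0.0731) did not pass. Igf2 passed the threshold without neonatal-supernatant library 3 (adjusted p = 0.0352).

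Neonatal tendon cells given adult T cell supernatant also raised interferon-gamma genes and lowered elastin and contractile genes. The largest rises were in Gbp4 (10.82 ± 1.08), Gbp6 (9.98 ± 0.59), Saa3 (9.92 ± 0.66), Nos2 (9.72 ± 0.38), Tgtp2 (9.29 ± 0.46) and H2-Q6 (9.24 ± 0.32), of which all but Saa3 and Nos2 have close relatives and are uncertain. Gbp4 was at 0.596 ± 0.812 CPM in media. The largest falls were in Eln (-7.15 ± 0.58), C1qtnf3 (-5.83 ± 0.21), Aspn (-5.74 ± 0.38), Myh11 (-5.57 ± 0.96) and Cdkn1c (-4.51 ± 0.30). Akap13, a scaffold of protein kinase A, was at 15.6 ± 18.8 CPM in media and 0.136 ± 0.0148 CPM with adult supernatant (mean ± SD, n = 3), and its fall missed the threshold without media library 2 (adjusted p = 0.203), media library 3 (0.125), adult-supernatant library 1 (0.0801), adult-supernatant library 2 (0.0884) or adult-supernatant library 3 (0.0885). The question is how neonatal cells respond to factors from adult T cells, and 6875 of 14391 genes passed the threshold, 4074 higher and 2801 lower, 3121 of them by at least 2-fold (2425 higher and 696 lower). At most, adjusted p reached 0.000134 for these genes apart from Akap13.

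Of the interferon-gamma genes, 25 of 25 rose, median 6.09 (camera adjusted p = 5.74e-18, with estimated correlation p = 0.0815), with Irf1 (5.03 ± 0.21), Cd274 (5.62 ± 0.28), Cxcl10 (7.21 ± 0.44) and Serping1 (6.09 ± 0.27). For type I interferon, 18 of 21 rose, median 3.38 (mean 3.43, or 4.40 without media library 1, camera adjusted p = 8.6e-05, with estimated correlation p = 0.389) and for MHC class I, 19 of 19 rose, median 4.00 (camera adjusted p = 5.65e-17, with estimated correlation p = 0.0815). Rtp4 and H2-Aa, at 0 in all media libraries, were at least 22.1-fold and 22.6-fold higher. Of the IL-17 targets, 15 of 15 rose, median 4.77 (camera adjusted p = 3.06e-11, with estimated correlation p = 0.0825). Il6 (8.40 ± 0.51), Lcn2 (8.58 ± 0.73), Ccl2 (4.30 ± 0.12), Mmp3 (5.87 ± 0.43), Mmp13 (3.53 ± 0.45) and Ptgs2 (1.81 ± 0.21) rose. The largest adjusted p of the genes named here was 2.62e-05.

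Of the tendon genes, 2 of 21 rose and 15 fell, median -0.65 (camera adjusted p = 1.5e-06, with estimated correlation p = 0.0815), with Scx (-1.42 ± 0.22), Tnmd (-2.85 ± 0.30), Fmod (-2.82 ± 0.13) and Ogn (-3.40 ± 0.25) falling and Tnc (2.13 ± 0.16) rising. Mkx did not pass (0.01, adjusted p = 0.981). For collagens, 8 of 29 rose and 19 fell, median -0.71 (camera adjusted p = 3.54e-05, with estimated correlation p = 0.151), with Col3a1 (-0.55 ± 0.15), Col6a3 (-2.79 ± 0.16) and Col5a1 (-1.96 ± 0.12). Col1a1 (-1.17 ± 0.10) fell, but was at 0.00 with quantile normalization (adjusted p = 1). For myofibroblast genes, 3 of 24 rose and 15 fell, median -0.95 (camera adjusted p = 6.33e-07, with estimated correlation p = 0.0825), with Acta2 (-2.03 ± 0.20) and Itga11 (-3.29 ± 0.20). The cell cycle list gave no call, as 2 of 32 rose and 7 fell (0 and 1 adjusted over the list alone, camera adjusted p = 0.0754), nor did Mki67 (-0.26, adjusted p = 0.256) and Igf2 (-0.92, adjusted p = 0.111) pass. The cell cycle list passed the threshold without adult-supernatant library 1 (adjusted p = 0.0125). Igf2 passed the threshold without media library 3 (adjusted p = 0.0212). Markers of other cell types moved as well: for macrophages, 9 of 14 rose and 1 fell (camera adjusted p = 0.0706), with Itgam (3.83 ± 0.47), and for mural cells, 6 of 7 fell (camera adjusted p = 0.000115, with estimated correlation p = 0.0815), with Pdgfrb (-1.64 ± 0.10). The macrophage list passed the threshold without media library 2 (adjusted p = 0.0401).

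Neonatal tendon cells given neonatal T cell supernatant, the pair matched in age, changed the fewest genes of the responses to supernatant. The largest rises were in Ccl11 (7.52 ± 0.31), C3 (6.05 ± 0.38), Il6 (5.61 ± 0.51), Ttn (5.61 ± 0.64), Saa3 (5.29 ± 0.66) and Il13ra2 (5.12 ± 0.43), and the largest falls in Eln (-5.77 ± 0.58), Aspn (-3.99 ± 0.38), Ptn (-3.15 ± 0.24), Col8a2 (-3.05 ± 0.38), Mest (-2.97 ± 0.35) and C1qtnf3 (-2.74 ± 0.21), which include the growth factor pleiotrophin and the imprinted gene Mest. Adjusted p was at most 2.05e-05 for these genes. In total, 2638 of 14391 genes passed the threshold, 1542 higher and 1096 lower, 968 of them by at least 2-fold (726 higher and 242 lower).

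Of the IL-17 targets, 13 of 15 rose (14 adjusted over the list alone), median 3.08 (camera adjusted p = 3.45e-16, with estimated correlation p = 0.0574), with Lcn2 (3.78 ± 0.73) and Cxcl5 (4.85 ± 0.28), at list levels of 5.08, 5.54 and 3.55 in libraries 1 to 3. Of the interferon-gamma genes, 9 of 25 rose, median 1.09 (camera adjusted p = 0.000468, with estimated correlation p = 0.426), with Irf1 (0.94 ± 0.21) and Cd274 (1.49 ± 0.28). Nos2 (1.45 ± 0.38) passed at adjusted p = 0.0126. The type I interferon list gave no call, as 1 of 21 rose and 1 fell (median -0.52, mean -0.38, camera adjusted p = 0.113). Without media library 1, where its level is high, the mean was 0.58 (adjusted p = 0.318). The type I interferon list passed the threshold without media library 2 (adjusted p = 0.0124) or media library 3 (0.00231). Nos2 missed the threshold without media library 2 (adjusted p = 0.0624) or neonatal-supernatant library 1 (0.0781). Ccl2 (3.68 ± 0.12), Mmp3 (3.65 ± 0.43) and Ptgs2 (1.06 ± 0.21) rose (largest adjusted p 0.00143). Cxcl10 (0.31, adjusted p = 0.696) and Mmp13 (0.96, adjusted p = 0.154) did not pass. Mmp13 passed the threshold without neonatal-supernatant library 3 (adjusted p = 0.00166).

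Tendon genes gave no list call with neonatal supernatant in neonatal cells, as 3 of 21 rose and 6 fell (3 and 7 adjusted over the list alone, camera adjusted p = 0.165), with Tnmd (-1.32 ± 0.30) falling and Prg4 (1.50 ± 0.12) and Comp (1.34 ± 0.11) rising. Scx (-0.34, adjusted p = 0.339), Mkx (0.57, adjusted p = 0.162), Col3a1 (0.01, adjusted p = 0.982), Acta2 (-0.45, adjusted p = 0.131) and Igf2 (-0.12, adjusted p = 0.892) did not pass. Col1a1 (-0.34 ± 0.10) fell at adjusted p = 0.0237, but was at 0.30 with quantile normalization (adjusted p = 0.107), where values follow rank alone. Col1a1 missed the threshold without media library 2 (adjusted p = 0.0607), media library 3 (0.0801), neonatal-supernatant library 1 (0.0723) or neonatal-supernatant library 3 (0.0671). Of the cell cycle genes, 17 of 32 fell (18 adjusted over the list alone), median -0.54 (camera adjusted p = 9.67e-08, with estimated correlation p = 0.177), with Mki67 (-0.63 ± 0.18). Mki67 missed the threshold without media library 3 (adjusted p = 0.127), neonatal-supernatant library 2 (0.051) or neonatal-supernatant library 3 (0.0954).

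Genes called with a supernatant in adult cells were often called in the same direction in neonatal cells. With adult supernatant, 3195 genes rose in both (1147 if the calls were independent, and 1732 with a mean of at least 3 log2 CPM), 2227 fell in both (669 if independent), and 15 and 29 genes that rose or fell in adult cells went the opposite way in neonatal cells. With neonatal supernatant, 1120 rose in both (249 if independent) and 686 fell in both (122 if independent), with 6 and 5 opposite. Over 9411 genes with a mean of at least 3 log2 CPM, the log2 fold changes with adult supernatant had a standard deviation of 0.94 in adult and 0.91 in neonatal cells, with Pearson's r = 0.93 and Spearman's rho = 0.83. With neonatal supernatant these were 0.52 and 0.43, with r = 0.79 and rho = 0.62. These correlations run across genes, which are not independent replicates.

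**Figure D3:**
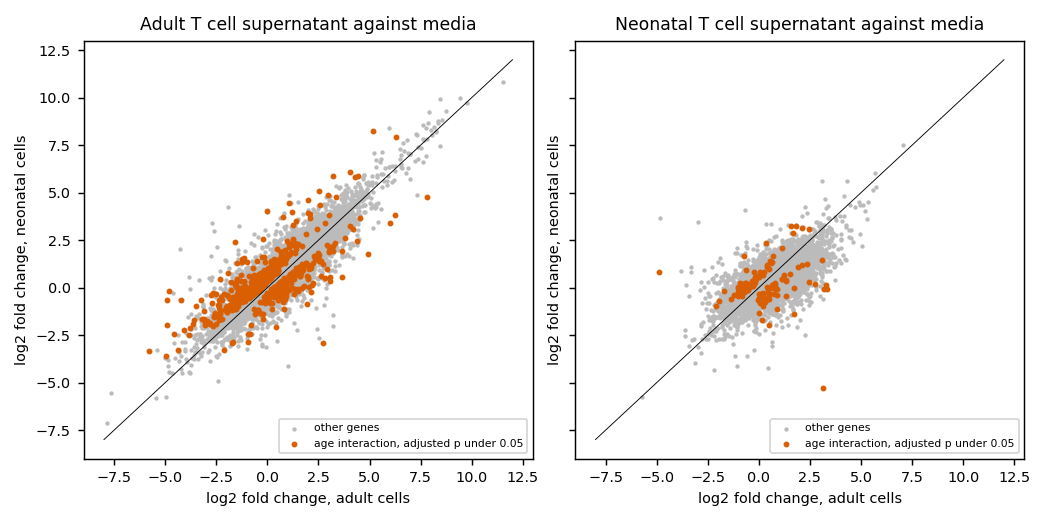
Log2 fold change with supernatant in neonatal cells (vertical) against that in adult cells (horizontal), 1 point for each of 14391 genes, for adult and for neonatal supernatant. Orange marks the 655 and 123 genes with a called interaction.

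On adult cells, interferon-gamma genes were lower with neonatal than with adult supernatant, and tendon and collagen genes were higher. With neonatal rather than adult supernatant, Gbp4 (-9.03 ± 1.08), Nos2 (-7.19 ± 0.38), Cxcl9 (-6.99 ± 0.46), Rarres2 (-6.93 ± 0.52), Gbp6 (-6.92 ± 0.59) and Gbp5 (-6.04 ± 0.44) were lowest, and Myh11 (5.78 ± 0.96), Gprin3 (4.03 ± 0.37), Col14a1 (3.87 ± 0.25), Slc5a7 (3.51 ± 0.19) and Arsi (3.31 ± 0.24) among the highest, including smooth muscle myosin and collagen XIV. Nos2 was at 3350 ± 204 CPM with adult and 26.1 ± 15 CPM with neonatal supernatant (mean ± SD, n = 3). At most, adjusted p reached 0.000174 for these genes. In total, 4110 of 14391 genes passed the threshold, 2171 higher and 1939 lower, 1167 of them by at least 2-fold (526 higher and 641 lower). Values are neonatal minus adult supernatant.

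For the interferon-gamma list, 24 of 25 were lower (25 adjusted over the list alone), at a median of -3.38 (camera adjusted p = 1.29e-19, with estimated correlation p = 0.0521), with Irf1 (-2.76 ± 0.21), Cd274 (-3.96 ± 0.28) and Cxcl10 (-5.93 ± 0.44). For MHC class I, 19 of 19 were lower (camera adjusted p = 1.34e-17, with estimated correlation p = 0.0695), and for oxidative stress, 10 of 13 were lower (11 adjusted over the list alone, camera adjusted p = 5.08e-10, with estimated correlation p = 0.015), the list call that held here with an estimated correlation. Of 19 NF-κB targets, 0 were higher and 14 lower (1 and 16 adjusted over the list alone, camera adjusted p = 5.83e-09, with estimated correlation p = 0.0629), with Ptgs2 (-1.76 ± 0.21). Il6 (-2.88 ± 0.51), Lcn2 (-3.43 ± 0.73) and Ccl2 (-0.62 ± 0.12) were lower. Mmp3 (-0.97, adjusted p = 0.104) and Mmp13 (-0.71, adjusted p = 0.259) did not pass. For tendon genes, 16 of 21 were higher and 2 were lower (16 and 3 adjusted over the list alone, camera adjusted p = 5.77e-08, with estimated correlation p = 0.0521), with Scx (1.36 ± 0.22), Mkx (1.34 ± 0.27), Comp (2.56 ± 0.11) and Fmod (2.09 ± 0.13) higher. Tnmd (0.83 ± 0.30) was higher at adjusted p = 0.0461. Tnmd missed the threshold without adult-supernatant library 2 (adjusted p = 0.128), adult-supernatant library 3 (0.105), neonatal-supernatant library 2 (0.229) or neonatal-supernatant library 3 (0.0692). For collagens, 21 of 29 were higher and 2 were lower (22 and 2 adjusted over the list alone, camera adjusted p = 2.99e-13, with estimated correlation p = 0.0521), with Col1a1 (1.16 ± 0.10), Col3a1 (1.18 ± 0.15) and Col6a1 (2.80 ± 0.11). For myofibroblast genes, 14 of 24 were higher and 2 were lower (15 and 2 adjusted over the list alone, camera adjusted p = 1.08e-06, with estimated correlation p = 0.105), with Acta2 (1.66 ± 0.20). Igf2 did not pass (0.26, adjusted p = 0.715).

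On neonatal cells, too, interferon-induced genes were lower with neonatal than with adult supernatant. With neonatal rather than adult supernatant, Gbp4 (-9.67 ± 1.08), Nos2 (-8.27 ± 0.38), Gbp6 (-7.92 ± 0.59), Cxcl9 (-7.74 ± 0.46), Gbp5 (-7.61 ± 0.44) and Tgtp2 (-7.56 ± 0.46) were lowest, and Myh11 (4.42 ± 0.96), C1qtnf3 (3.09 ± 0.21), Thbs4 (2.96 ± 0.28), Arsi (2.91 ± 0.24) and Aqp5 (2.90 ± 0.33) among the highest, including thrombospondin 4, a tendon matrix protein, and the water channel aquaporin 5. The largest adjusted p of these genes was 0.00217. In total, 4659 of 14391 genes passed the threshold, 1969 higher and 2690 lower, 1688 of them by at least 2-fold (310 higher and 1378 lower). Quantile normalization turned that split to 3004 higher and 1889 lower (61.4% higher), and a mean of at least 3 log2 CPM to 1787 and 1624.

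For interferon-gamma genes, 25 of 25 were lower, at a median of -5.18 (camera adjusted p = 5.49e-26, with estimated correlation p = 0.0447), with Irf1 (-4.09 ± 0.21), Cd274 (-4.13 ± 0.28) and Cxcl10 (-6.90 ± 0.44). For MHC class I, 19 of 19 were lower (camera adjusted p = 4.42e-24, with estimated correlation p = 0.0447), for MHC class II, 5 of 7 were lower (6 adjusted over the list alone, camera adjusted p = 0.000167, with estimated correlation p = 0.0413), and for type I interferon, 20 of 21 were lower (camera adjusted p = 1.51e-09, with estimated correlation p = 0.234). For IL-17 targets, 12 of 15 were lower (camera adjusted p = 5.75e-06, with estimated correlation p = 0.247), with Il6 (-2.79 ± 0.51) and Lcn2 (-4.80 ± 0.73). Ccl2 (-0.62 ± 0.12), Mmp3 (-2.22 ± 0.43) and Mmp13 (-2.56 ± 0.45) were lower. Ptgs2 (-0.75 ± 0.21) was lower at adjusted p = 0.0113 (0.0698 without neonatal-supernatant library 3). For tendon genes, 14 of 21 were higher and 3 were lower (camera adjusted p = 6.55e-08, with estimated correlation p = 0.0447), with Scx (1.08 ± 0.22), Tnmd (1.53 ± 0.30), Prg4 (2.68 ± 0.12) and Comp (1.90 ± 0.11) higher. Mkx (0.56, adjusted p = 0.125), Igf2 (0.79, adjusted p = 0.202) and Mki67 (-0.36, adjusted p = 0.144) did not pass. For cartilage and bone, 5 of 9 were higher (camera adjusted p = 0.000339, with estimated correlation p = 0.0447), with Sox9 (1.12 ± 0.11), and Sp7 was at least 8.44-fold higher. For oxidative stress, 8 of 13 were lower (camera adjusted p = 3.75e-05, with estimated correlation p = 0.0447). The 6 list calls that held with an estimated correlation here were interferon-gamma, MHC class I, MHC class II, tendon, cartilage and bone, and oxidative stress. Acta2 (1.58 ± 0.20) and Col3a1 (0.56 ± 0.15) were higher, and Col3a1 missed the threshold without neonatal-supernatant library 2 (adjusted p = 0.0577). Col1a1 (0.83 ± 0.10) was higher, but at 0.30 with quantile normalization (adjusted p = 0.063).

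Without supernatant, neonatal tendon cells expressed far more Scx, a transcription factor of tendon progenitors, and less Cxcl12 and Ccl8 than adult cells. Scx was at 353 ± 33.7 CPM in neonatal and 15.9 ± 3.99 CPM in adult cells in media (mean ± SD, n = 3), a log2 difference of 4.50 ± 0.22. Ngfr (4.94 ± 0.40) and Ifi202b (5.50 ± 0.54), a neurotrophin receptor and an interferon-inducible gene, were higher, and Gdf10 (-3.78 ± 0.33), Lbp (-3.53 ± 0.26), Dpt (-3.47 ± 0.47), Cxcl12 (-3.45 ± 0.15) and Ccl8 (-3.37 ± 0.21) were among the lowest, among them dermatopontin, a matrix protein, and the chemokine Cxcl12. Adjusted p was at most 4.56e-05 for these genes. Also among the 6 largest differences upwards were Rps2-ps10 (7.00 ± 0.46), Rpl34-ps1 (6.82 ± 0.21) and Rps2-ps6 (5.76 ± 0.46), named as near-identical copies of other genes and therefore uncertain. In total, 4122 of 14391 genes passed the threshold, 2398 higher and 1724 lower, 890 of them by at least 2-fold (381 higher and 509 lower). TMM scaling turned that split to 1884 higher and 2109 lower (47.2% higher). The count was 2322 without both media libraries of high type I level, an alternative chosen after seeing the data.

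For the cell cycle, 26 of 32 were higher (28 adjusted over the list alone), at a median of 1.06 (camera adjusted p = 6.91e-14, with estimated correlation p = 0.0895), with Mki67 (1.07 ± 0.18), Aurka (1.39 ± 0.15) and Tpx2 (1.31 ± 0.12) higher in neonatal cells. For fetal growth and imprinted genes, 9 of 12 were higher (camera adjusted p = 9.11e-06, with estimated correlation p = 0.0254), with Igf2 (2.21 ± 0.46), Igf2bp2 (0.74 ± 0.07) and Hmga2 (1.14 ± 0.07). Without those libraries, Igf2 and Acta2 missed the threshold (adjusted p = 0.0519 and 0.0646). For proteases and inhibitors, 1 of 26 was higher and 15 were lower (1 and 16 adjusted over the list alone, camera adjusted p = 3.71e-08, with estimated correlation p = 0.0274), with Mmp3 (-3.61 ± 0.43) and Adamts2 (-1.46 ± 0.14). The fetal growth and protease calls were the ones that held with an estimated correlation. For chemokines, 0 of 15 were higher and 7 were lower (1 and 7 adjusted over the list alone, camera adjusted p = 0.000309, with estimated correlation p = 0.267), for NF-κB targets, 1 of 19 was higher and 7 were lower (camera adjusted p = 0.00031, with estimated correlation p = 0.267) and for MHC class I, 5 of 19 were lower (camera adjusted p = 0.000433, with estimated correlation p = 0.499). For type I interferon, 1 of 21 was lower (camera adjusted p = 0.0434, with estimated correlation p = 0.778). The type I interferon list missed the threshold without adult-cell media library 2 (adjusted p = 0.45), neonatal-cell media library 2 (0.248) or neonatal-cell media library 3 (0.55). For collagens, 4 of 29 were higher and 11 were lower (5 and 11 adjusted over the list alone, not adjusted for gene length, camera adjusted p = 0.017, with estimated correlation p = 0.499), with Col3a1 (-1.13 ± 0.15) and Col14a1 (-2.41 ± 0.25) lower. The collagen list missed the threshold without neonatal-cell media library 1 (adjusted p = 0.0604). Mkx (1.18 ± 0.27), Acta2 (0.82 ± 0.20) and Ptgs2 (0.94 ± 0.21) were higher.

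Mmp13 (-1.42 ± 0.45), Il6 (-1.63 ± 0.51), Irf1 (-0.70 ± 0.21) and Cd274 (-0.89 ± 0.28) were lower in neonatal cells in media (adjusted p = 0.0246, 0.0238, 0.0194 and 0.0251), but each depended on single libraries. Mmp13 missed the threshold without adult-cell media library 2 (adjusted p = 0.13) or neonatal-cell media library 2 (0.102). Il6 missed the threshold without adult-cell media library 1 (adjusted p = 0.0954), adult-cell media library 3 (0.0653), neonatal-cell media library 1 (0.0641) or neonatal-cell media library 3 (0.128). Irf1 missed the threshold without adult-cell media library 2 (adjusted p = 0.0647), neonatal-cell media library 1 (0.0598) or neonatal-cell media library 2 (0.0768). Cd274 missed the threshold without adult-cell media library 1 (adjusted p = 0.0622), adult-cell media library 2 (0.0815), neonatal-cell media library 2 (0.0652) or neonatal-cell media library 3 (0.125). Tnmd (0.74, adjusted p = 0.0755), Col1a1 (0.08, adjusted p = 0.61), Ccl2 (-0.25, adjusted p = 0.157), Cxcl10 (-0.81, adjusted p = 0.194), Nos2 (-0.84, adjusted p = 0.111) and Lcn2 (-0.91, adjusted p = 0.392) did not pass. Tnmd passed the threshold without neonatal-cell media library 3 (adjusted p = 0.0372). Cxcl10 passed the threshold without neonatal-cell media library 1 (adjusted p = 0.0112). Il6 was at -1.31 with quantile normalization (adjusted p = 0.0578) and Cd274 at -0.70 with quantile normalization (adjusted p = 0.0585).

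Markers of other cell types differed between the ages in media. For Schwann cells, 4 of 6 were higher (5 adjusted over the list alone, camera adjusted p = 0.000309, with estimated correlation p = 0.0895), with Cdh19 (4.68 ± 0.59), Foxd3 (4.03 ± 0.51) and Sox10 (4.46 ± 0.70), transcription factors and an adhesion molecule of the neural crest lineage. The level of the list in neonatal cells in media was 2.42, 2.38 and 3.90 log2 CPM in libraries 1 to 3. For macrophages, 7 of 14 were lower (8 adjusted over the list alone, camera adjusted p = 0.000119, with estimated correlation p = 0.165), with C1qa (-2.65 ± 0.43), C1qb (-2.19 ± 0.34) and Lyz2 (-1.37 ± 0.20). For endothelium, 8 of 10 were lower (camera adjusted p = 0.000117, with estimated correlation p = 0.0895), with Pecam1 (-2.24 ± 0.37), Cdh5 (-2.41 ± 0.44) and Tie1 (-2.95 ± 0.37).

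The interaction with adult supernatant asks whether neonatal cells respond differently from adult cells, as the neonatal response minus the adult response. A positive value means that the gene rose more or fell less in neonatal cells. Sfrp1 (2.66 ± 0.18), Col14a1 (4.25 ± 0.35) and C1s1 (2.60 ± 0.25) were positive, a Wnt antagonist, collagen XIV and a complement protease. Sema7a (-2.49 ± 0.18), Nid1 (-1.48 ± 0.12), Spp1 (-1.41 ± 0.20) and Hmox1 (-0.83 ± 0.10) were negative, a semaphorin, the basement membrane protein nidogen, osteopontin and heme oxygenase. Another 12 genes with the smallest p were Slc44a2 (1.78 ± 0.13), Xdh (1.75 ± 0.13), Igfbp4 (1.56 ± 0.13), Gas6 (1.17 ± 0.10), Heg1 (1.23 ± 0.12) and Figf (1.32 ± 0.13) with positive and Hmga2 (-0.97 ± 0.10), Fam20c (-1.28 ± 0.18), Rasa1 (-0.70 ± 0.10), Igf2bp2 (-0.69 ± 0.10), Tmcc3 (-1.06 ± 0.15) and Prdx1 (-0.92 ± 0.13) with negative values, the largest adjusted p of these being 0.00071. In total 655 of 14391 genes passed the threshold, 432 positive and 223 negative, 211 of them by at least 2-fold (142 positive and 69 negative). The count was 406 without adult-cell adult-supernatant library 1, 418 without neonatal-cell adult-supernatant library 3 and 434 without neonatal-cell media library 2, and 360 without both media libraries of high type I level.

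For cholesterol synthesis, 8 of 20 were positive (12 adjusted over the list alone), at a median of 0.46 (camera adjusted p = 1.27e-07, with estimated correlation p = 0.275), with Hmgcs1 (0.79 ± 0.12), Insig1 (0.77 ± 0.14), Nsdhl (1.00 ± 0.17) and Sqle (0.61 ± 0.13). For oxidative stress, 0 of 13 were positive and 5 negative (1 and 7 adjusted over the list alone, camera adjusted p = 2.76e-06, with estimated correlation p = 0.0772), with Slc7a11 (-1.03 ± 0.21) and Srxn1 (-0.59 ± 0.13). For p53 and senescence, 4 of 18 were positive and 0 negative (12 and 1 adjusted over the list alone, camera adjusted p = 0.000162, with estimated correlation p = 0.275). For IL-17 targets, 2 of 15 were positive (3 adjusted over the list alone, camera adjusted p = 0.000983, with estimated correlation p = 0.591), and for chemokines, 3 of 15 were positive (5 adjusted over the list alone, camera adjusted p = 0.0201, with estimated correlation p = 0.591), with Ccl8 (1.65 ± 0.30). The chemokine list missed the threshold without adult-cell media library 2 (adjusted p = 0.0624), adult-cell adult-supernatant library 2 (0.141) or neonatal-cell media library 3 (0.0887). The interferon-gamma and MHC class I lists gave no call, as 1 of 25 was positive (camera adjusted p = 0.367) and 0 of 19 were positive (camera adjusted p = 0.0807). The interferon-gamma list passed the threshold without neonatal-cell media library 1 (adjusted p = 0.00646). The MHC class I list passed the threshold without adult-cell media library 1 (adjusted p = 0.0384), adult-cell media library 3 (0.0432), adult-cell adult-supernatant library 3 (0.0401) or neonatal-cell media library 1 (0.00295). The 18 genes named beforehand whatever their values (Scx, Tnmd, Mkx, Col1a1, Col3a1, Acta2, Mmp3, Mmp13, Il6, Ccl2, Cxcl10, Ptgs2, Nos2, Irf1, Cd274, Lcn2, Igf2 and Mki67) did not pass, with adjusted p from 0.0644 (Il6, 2.43 ± 0.72) to 0.99 (Mkx, -0.02 ± 0.38). Il6 passed the threshold without neonatal-cell media library 2 (adjusted p = 0.0076). Col1a1 passed the threshold without adult-cell adult-supernatant library 2 (adjusted p = 0.0445). Acta2 passed the threshold without adult-cell media library 2 (adjusted p = 0.0194). Mki67 passed the threshold without adult-cell media library 3 (adjusted p = 0.0359) or neonatal-cell media library 3 (0.0263).

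With neonatal supernatant, neonatal and adult cells differed in fewer genes. Sfrp1 (1.70 ± 0.18), Xdh (1.18 ± 0.13), Igfbp4 (1.00 ± 0.13) and Figf (0.94 ± 0.13) were positive, and so were Adra1d (1.02 ± 0.14), Fam115c (0.59 ± 0.08), Sema3c (1.08 ± 0.16), Tsku (0.72 ± 0.10), Cdkn1a (0.56 ± 0.08) and Ak1 (0.39 ± 0.06), while Sema7a (-2.04 ± 0.18), Pdia5 (-0.58 ± 0.08), Gcnt4 (-1.86 ± 0.29), Adcy7 (-1.13 ± 0.18), Gpr124 (-0.92 ± 0.15) and Raph1 (-0.93 ± 0.16) were negative. Cdkn1a encodes the cell cycle inhibitor p21. At most, adjusted p reached 0.0171 for these. Spp1 (-1.14 ± 0.20), Prl2c2 (-1.64 ± 0.29), Nupr1 (-0.81 ± 0.15) and Fam46a (-1.13 ± 0.21) were negative as well. Spp1 and Prl2c2 missed the threshold without adult-cell neonatal-supernatant library 2 (adjusted p = 0.0503 and 0.0588). Nupr1 missed the threshold without neonatal-cell neonatal-supernatant library 1 (adjusted p = 0.053). Fam46a missed the threshold without adult-cell media library 3 (adjusted p = 0.0582), adult-cell neonatal-supernatant library 2 (0.063), neonatal-cell media library 1 (0.0513) or neonatal-cell neonatal-supernatant library 1 (0.0585). In total 123 of 14391 genes passed the threshold, 71 positive and 52 negative, 38 of them by at least 2-fold (17 positive and 21 negative).

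For the cell cycle, 1 of 32 was negative (17 adjusted over the list alone), at a median of -0.67 (camera adjusted p = 2.55e-13, with estimated correlation p = 0.249). For p53 and senescence, 3 of 18 were positive (12 adjusted over the list alone, camera adjusted p = 7.9e-12, with estimated correlation p = 0.0611). Camera called the interferon lists, but without a member past the threshold among all genes: for interferon-gamma, 0 of 25 were negative (5 adjusted over the list alone), at a median of -1.37 (camera adjusted p = 1.13e-07, with estimated correlation p = 0.541), and for type I interferon, 0 of 21 were negative (1 adjusted over the list alone), at a median of -1.93 and a mean of -1.89, or -0.92 without neonatal-cell media library 1 (camera adjusted p = 5.8e-07, with estimated correlation p = 0.659). For MHC class I, 0 of 19 were negative (5 adjusted over the list alone, camera adjusted p = 8.49e-09, with estimated correlation p = 0.541). The media library with the high type I level is library 1 in neonatal cells and library 2 in adult cells, and the type I level with neonatal supernatant was 3.77, 4.43 and 2.12 in adult cells and 0.73, 0.63 and 1.06 in neonatal cells. These 18 genes named beforehand did not pass, with adjusted p from 0.111 (Il6, 2.53 ± 0.72) to 0.92 (Lcn2, -0.40 ± 1.04). Irf1 passed the threshold without adult-cell neonatal-supernatant library 3 (adjusted p = 0.00127). Il6 passed the threshold without neonatal-cell media library 2 (adjusted p = 0.0213). The count of genes was 33 without adult-cell neonatal-supernatant library 2, 48 without neonatal-cell neonatal-supernatant library 1, 51 without adult-cell media library 3, 54 and 60 without neonatal-cell media libraries 2 and 1, 73 without adult-cell neonatal-supernatant library 1, and 228 (92 positive and 136 negative, the reverse of the split of all libraries) without adult-cell neonatal-supernatant library 3. It was 59 without both media libraries of high type I level.

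**Figure D4:**
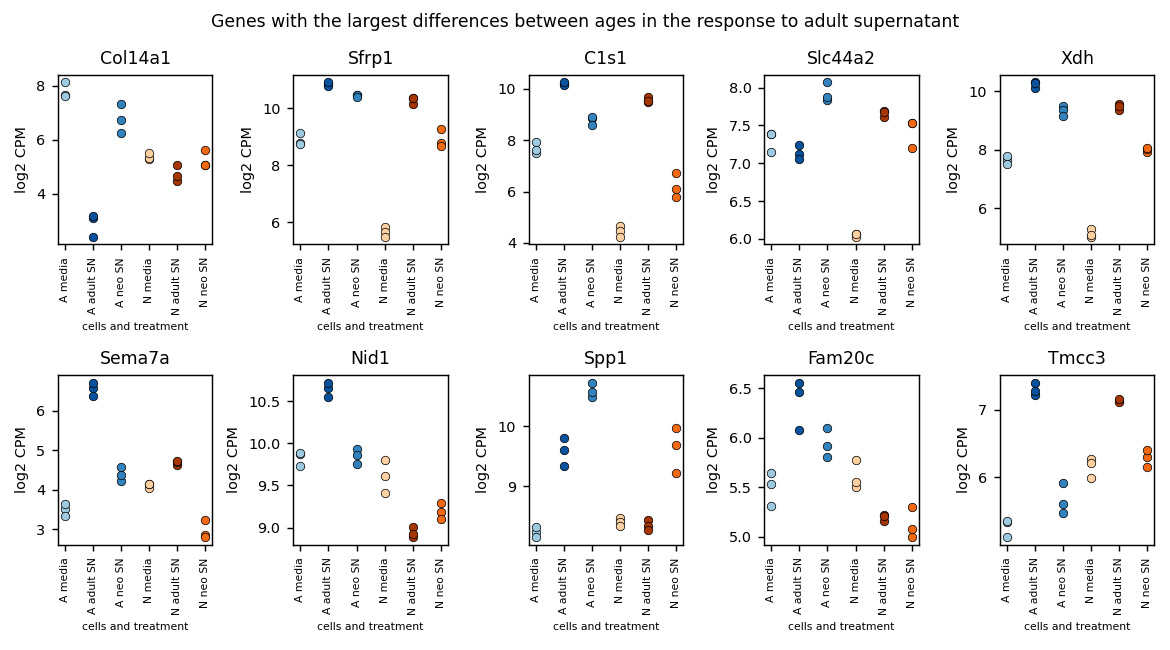
Log2 CPM per library in the 6 groups for 10 of the genes named for the interaction with adult supernatant (A, adult and N, neonatal cells; SN, supernatant), with 1 point per library. Sfrp1 differed in response by 2.66 with adult and 1.70 with neonatal supernatant.

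**Figure D5:**
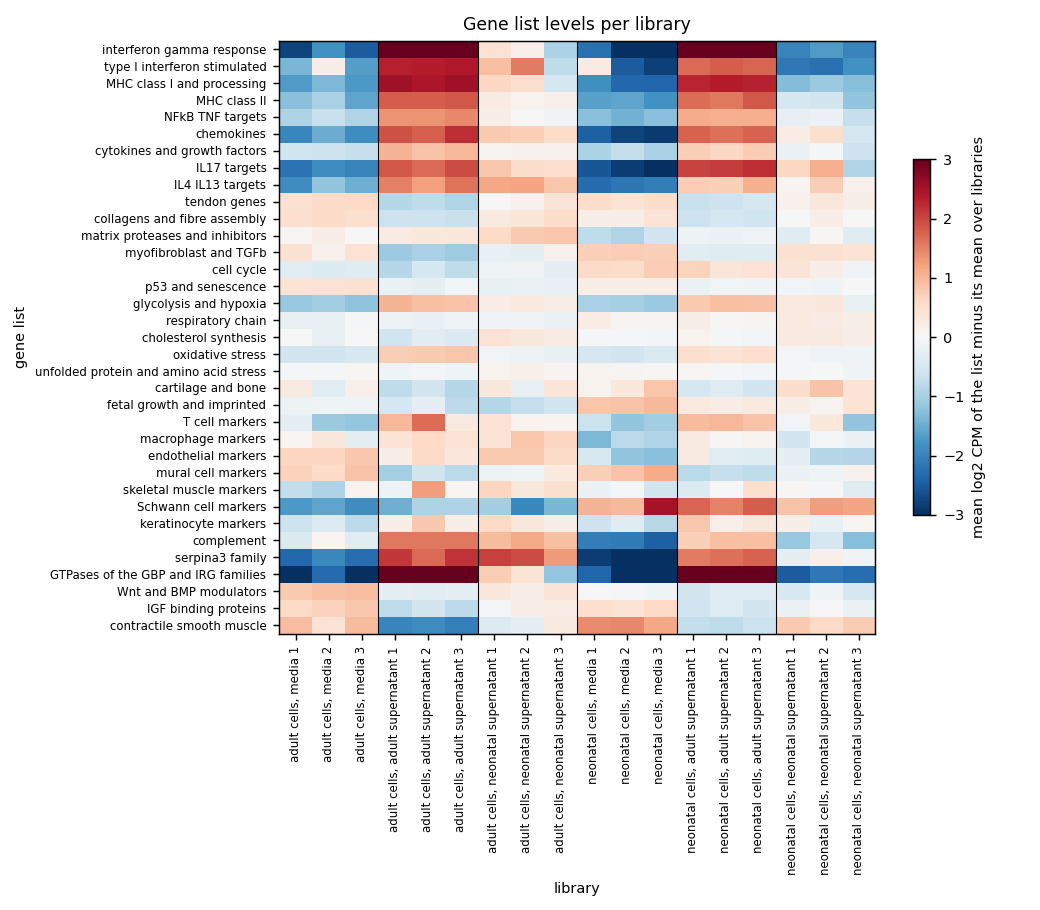
Mean log2 CPM of each gene list in each library minus its mean over the libraries, as a colour scale from -3 to 3, with the 6 lists chosen after seeing the data at the bottom. The type I interferon list stands higher in library 2 of adult cells in media and library 1 of neonatal cells in media than in the other media libraries.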

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

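The splits of the libraries and their counts were planned. The tests of the 3 patterns below, on genes apart by age, on interferon-stimulated genes in media and on genes silent in media, were chosen only after the result was seen. The interaction with adult supernatant stood out because a test of the difference between the responses of neonatal and adult cells called 655 genes. The additive effects of age and supernatant were removed before libraries were split by age within each treatment. In 1 of 100 drawn splits, the real one, as many genes were called, and the highest of the others was 3. The count thus exceeded those of the other drawn splits. Reading this as more than chance requires independent libraries within a group, which the labels do not state. For the interaction with neonatal supernatant the real count of 123 was likewise reached in 1 of 100 drawn splits, and the highest of the others was 55. Reading that count as more than chance requires the same independence of libraries. The count was 33 to 228 without 1 library, 29 with no trend and 39 with only the compared groups, where no splits were drawn. For comparisons of 3 against 3 libraries the 10 splits are too few to judge chance. The real counts of 7490 and 3929 in adult cells, 6875 and 2638 in neonatal cells, 4110 and 4659 between supernatants and 4122 between ages stood against highest others of 0 and 1, 0 and 0, 1 and 0, and 0.

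Genes whose response to adult supernatant differed between the ages, as neonatal minus adult log2 fold change, were Sfrp1 (2.66), Slc44a2 (1.78), Xdh (1.75), Igfbp4 (1.56), Col14a1 (4.25), Gas6 (1.17), C1s1 (2.60), Heg1 (1.23) and Figf (1.32) with positive and Sema7a (-2.49), Nid1 (-1.48), Hmga2 (-0.97), Hmox1 (-0.83), Fam20c (-1.28), Rasa1 (-0.70), Spp1 (-1.41), Igf2bp2 (-0.69), Tmcc3 (-1.06) and Prdx1 (-0.92) with negative values. Among list examples Ccl8 (1.65), Hmgcs1 (0.79), Nsdhl (1.00), Insig1 (0.77) and Sqle (0.61) were positive and Slc7a11 (-1.03) and Srxn1 (-0.59) negative. Lists that differed by camera had mean values of 0.69 for chemokines, 1.05 for IL-17 targets, 0.30 for p53, 0.44 for cholesterol synthesis, 0.71 for macrophage markers, 1.16 for endothelial markers, -0.17 for glycolysis, -0.35 for oxidative stress and -0.21 for fetal growth. With an estimated correlation their adjusted p ran from 0.0772 to 0.743. The chemokine list missed the threshold without adult-cell media library 2 (adjusted p = 0.0624), adult-cell adult-supernatant library 2 (0.141) or neonatal-cell media library 3 (0.0887). The glycolysis list missed the threshold without adult-cell media library 3 (adjusted p = 0.0566), adult-cell adult-supernatant library 1 (0.062) or neonatal-cell adult-supernatant library 1 (0.0531). The macrophage list missed the threshold without adult-cell media library 2 (adjusted p = 0.137), adult-cell adult-supernatant library 1 (0.065), adult-cell adult-supernatant library 2 (0.0825), neonatal-cell media library 1 (0.112), neonatal-cell media library 3 (0.0518) or neonatal-cell adult-supernatant library 1 (0.1). The fetal growth list missed the threshold without adult-cell adult-supernatant library 2 (adjusted p = 0.0742).

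With neonatal supernatant the positive genes were Sfrp1 (1.70), Xdh (1.18), Igfbp4 (1.00), Adra1d (1.02), Fam115c (0.59), Figf (0.94), Sema3c (1.08), Tsku (0.72), Cdkn1a (0.56) and Ak1 (0.39), and the negative ones Sema7a (-2.04), Pdia5 (-0.58), Gcnt4 (-1.86), Adcy7 (-1.13), Gpr124 (-0.92), Spp1 (-1.14), Raph1 (-0.93), Prl2c2 (-1.64), Nupr1 (-0.81) and Fam46a (-1.13). Spp1 and Prl2c2 missed the threshold without adult-cell neonatal-supernatant library 2 (adjusted p = 0.0503 and 0.0588). Nupr1 missed the threshold without neonatal-cell neonatal-supernatant library 1 (adjusted p = 0.053). Fam46a missed the threshold without adult-cell media library 3 (adjusted p = 0.0582), adult-cell neonatal-supernatant library 2 (0.063), neonatal-cell media library 1 (0.0513) or neonatal-cell neonatal-supernatant library 1 (0.0585). Lists that differed by camera had mean values of -1.23 for interferon-gamma, -1.89 for type I interferon (-0.92 without neonatal-cell media library 1), -0.82 for MHC class I, -0.66 for the cell cycle, 0.37 for p53, -0.20 for glycolysis and -0.22 for unfolded-protein stress, and adjusted p from 0.0611 to 0.659 with an estimated correlation. The glycolysis list missed the threshold without adult-cell media library 3 (adjusted p = 0.0858), neonatal-cell media library 1 (0.0744), neonatal-cell media library 2 (0.0531) or neonatal-cell neonatal-supernatant library 3 (0.662).

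In cells of every treatment, 19 genes were higher in all neonatal than in all adult libraries by more than 2 log2 units and 1 was lower, where chance separates 9 libraries from 9 completely for a share of 4.11e-05 of genes. Of the 18 found in the reference (GRCm38), 12 have a near-identical transcript of another gene, against 39 of 441 genes matched in level (8.84%, Fisher's exact test, p = 1.13e-08), while 6 have none (Crabp1, Cxcl12, Fabp2, Ifi202b, Ngfr and Scx), which argues against reads shared with a near-identical gene for those 6. For the 12, shared reads and real expression of the copies cannot be told apart: the source gene was lower by at least 0.5 of the copy's gain in 2 of 6 cases, as for Rpl34 (173 CPM in adult, 76.9 CPM in neonatal media) beside Rpl34-ps1 (0.371 and 54.8 CPM), but Kpna2 stayed at 87.4 and 87.2 CPM while Gm10184 went from 0.499 to 47.4 CPM. Of the 18 genes 2 lie on the X chromosome (Gm6206 and Gm6472) and 0 on the Y chromosome, which argues against the sex make-up of the pooled donors. The age of the donors, and a difference in strain, which the labels do not state and under which Ifi202b is known to vary, stay open and untested.

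Interferon-stimulated genes were high in 1 of 3 media libraries at each age, library 2 of adult cells and library 1 of neonatal cells. Mixing with adult-supernatant libraries would raise all genes induced there alike. But 50 other induced genes stood at a median of 0.141% and 0.0848% of their increment (adult- and neonatal-cell library). Interferon genes stood at 13.6% and 32.5%. Macrophage markers differed by -0.500 log2 units in the neonatal-cell library from the mean of the other 2, which argues against macrophages in the culture there, while in the adult-cell library the difference was 0.43, from which macrophages cannot be told apart from other sources. A trace of supernatant need not raise all genes alike. That and a type I interferon response in single wells stay open and untested, with 1 library at each age.

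The 64 odorant and vomeronasal receptor genes in the table, known from other tissues, summed to 37.2 CPM in adult cells in media and 439 CPM with adult supernatant. Genes risen from silence outnumbered those fallen to it by at least 2.43 to 1 over the 4 responses. The largest two-sided binomial p was 0.000535, genes taken as independent. The filter treats both alike, but the receptor genes were picked as risen, so this count cannot judge them. Genomic DNA or another background even along the genome cannot be told apart: 63 of 1477 annotated receptor genes (4.27%) are in the table, but the filter of the table would also leave out most genes under such a background of less than 1 CPM. T cell RNA carried in the supernatant cannot be told apart, as the filter limits its markers too. Of 18 T cell markers fixed beforehand 6 are in the table, and Cd3e, Cd2, Ifng and Il2 are not. Nor can the gains tell, since the receptor genes were picked as risen. In adult cells with adult supernatant their median was 2.36 CPM, against 1.14 CPM for T cell markers. The filter, an even background, T cell RNA and transcription in the tendon cells stay open.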

How the results depend on the processing

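The comparisons, gene lists, naming rule and most alternatives were fixed before the data were examined. Leaving out both media libraries of high type I level, and keeping only genes with a mean of at least 3 log2 CPM, were chosen after seeing the data. Asking for at least 2-fold lowered each count by construction: to 3424 and 1626 in adult cells, 3121 and 968 in neonatal cells, 1167 and 1688 between supernatants, 890 between ages, and 211 and 38 for the interactions. Counts stayed within 1.5 times under TMM scaling, quantile normalization, pseudocounts of 0.1 and 1 CPM and a filter of 5 CPM in 3 libraries. With a mean of at least 3 log2 CPM, and so fewer genes, the count for neonatal cells with adult supernatant was 4564. Without both media libraries it was 2322 between ages, 360 for the interaction with adult and 59 for that with neonatal supernatant. Array weights gave 1242 and 209 for the interactions, and for neonatal supernatant no trend gave 29 and only the compared groups 39; the cause was not tested.

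Leaving out 1 library gave 6804 to 7182 and 2995 to 3719 genes in adult cells, 5990 to 6400 and 1823 to 2546 in neonatal cells, 3273 to 3880 and 3336 to 4167 between supernatants, 2966 to 3827 between ages, 406 to 745 for the interaction with adult supernatant (lowest and highest without libraries 1 and 2 of adult cells with adult supernatant) and 33 to 228 for that with neonatal supernatant (libraries 2 and 3 of adult cells with neonatal supernatant). Replicate numbers carried no pairing: residuals of same-number libraries had a mean r of 0.00 over 45 pairs, from -0.21 to 0.23, against -0.33 to 0.26 for 90 others. With a replicate block in the order of the report's comparisons the counts were 7429, 3876, 6812, 2574, 4032, 4590, 4031, 645 and 115. Among named genes, 1101 of 1108 results kept direction and side of the threshold under TMM scaling, 1054 under quantile normalization, 1086 with a pseudocount of 1 CPM, 1070 with no trend, and 7591 of 8058 without 1 library. Quantile normalization reversed a pair of them: Cdh1 in neonatal cells with adult supernatant (1.41, then -0.04) and Col1a1 in neonatal cells with neonatal supernatant (-0.34, then 0.30); the cause was not tested. Of 252 list results, called or not, 249 stayed so under TMM scaling and 213 with fry. With an estimated correlation, 131 calls were lost. Using no filter could not be tried, since every deposited gene already has 1 CPM in 3 libraries. Depth limits genes near 3 reads, or 0.169 to 0.237 CPM, below which no difference is detectable.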

Other observations

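The 6 gene lists below, and their tests, were chosen after seeing the data. Each camera p, then that with estimated correlation, is adjusted over these 6 alone, more lightly than for earlier lists. In adult cells, genes of the complement system responded to adult supernatant: 10 of 15 rose and 1 fell (camera adjusted p = 0.000246, with estimated correlation p = 0.112), and in neonatal cells 13 of 15 rose and 1 fell (14 and 1 adjusted over the list alone, camera adjusted p = 7.3e-08, with estimated correlation p = 0.0333). In media, 14 of 15 were lower (15 adjusted over the list alone, camera adjusted p = 7.21e-14, with estimated correlation p = 0.0129) in neonatal cells, and 5 of 15 were positive (8 adjusted over the list alone) for the interaction with adult supernatant (camera adjusted p = 9.25e-09, with estimated correlation p = 0.0532). Of the Serpina3 family of protease inhibitors, whose members are similar and uncertain one by one, 7 of 7 rose in adult cells with adult supernatant (camera adjusted p = 6.35e-06, with estimated correlation p = 0.0449) and 7 of 7 rose with neonatal supernatant (camera adjusted p = 5.22e-11, with estimated correlation p = 0.017). Of the interferon-inducible GTPases of the Gbp and Irg families, 17 of 17 rose in adult cells with adult supernatant (camera adjusted p = 1.39e-12, with estimated correlation p = 0.0449).

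Of the contractile smooth muscle genes, 11 of 12 fell in adult cells with adult supernatant (camera adjusted p = 3.58e-08, with estimated correlation p = 0.0449) and 11 of 12 fell in neonatal cells (camera adjusted p = 2.34e-08, with estimated correlation p = 0.0333). Of the Wnt and BMP modulators, 9 of 17 were lower (12 adjusted over the list alone, camera adjusted p = 3.79e-06, with estimated correlation p = 0.0125) in neonatal cells in media. Of the list of IGF binding proteins, which also holds Pappa and Pappa2, proteases that cleave them, and Ccn3, 2 of 9 rose and 6 fell in adult cells with adult supernatant (camera adjusted p = 0.0024, with estimated correlation p = 0.0447) and 5 of 9 were higher and 1 was lower (camera adjusted p = 0.000508, with estimated correlation p = 0.0151) with neonatal rather than adult supernatant. These lists share members with those fixed earlier, such as Acta2 and the Gbp genes. The complement list holds C1qa, C1qb and C1qc, which are also macrophage markers, and of the macrophage markers 7 of 14 were lower in neonatal cells in media. The age difference in media fell with the length of the gene, at Spearman's rho of -0.25 over 4325 genes of 4 to 6 log2 CPM and -0.33 over 3069 genes of at least 6 log2 CPM, across genes that are not independent replicates, and no list was adjusted for it.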
